A study of Mus musculus with 9 samples.

How the data were processed

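The series holds 9 small RNA libraries of exosomes from RAW264.7 mouse macrophages, 3 each from untreated cells, cells with silica for 24 h and cells with silica for 48 h. Per the labels' protocols, the cells grew in medium with fetal bovine serum, exosomes were collected by ultracentrifugation, total RNA was taken with Trizol and libraries followed the BGISEQ-500 protocol. The series' design text calls the 3 libraries of a group independent repetitions. No batch or date is given in the labels. The submitters' processing notes name Trim Galore, Bowtie and HTSeq and the genome build mm10, with no versions, and how reads that match several miRNAs were assigned is not given in the sources used here.

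Each library has its own deposited table. Per the file headers, it gives the count of reads for each small RNA, and the whole numbers in the count column add up to the total in the header. The second deposited column, which the file headers call TPM, is the count divided by that total and scaled to RPM (matched within 0.005), with no length correction. It was not tested, because the counts were there. A miRNA that a table does not list was taken as 0 counts, since mature miRNAs are listed from 1 count. The tables also hold 14 RNA classes, of which known mature miRNAs were analysed one by one and the others as shares of all counted reads; predicted miRNAs outside the known set are listed from 10 counts.

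Groups were taken from the labels. The comparisons, tests, lists and the rule for which miRNAs to name were fixed before the data were examined. Of 1101 mature miRNAs, edgeR's filterByExpr with a minimum count of 10 kept 453, which hold at least 99.96% of the mature counts of each library. Counts were scaled by TMM (factors 0.829 to 1.16) and tested with edgeR's quasi-likelihood test in one fit over all 9 libraries with 6 residual degrees of freedom and no block. Adjusted p-values are Benjamini-Hochberg over the 453 miRNAs, with a threshold of 0.05. The square root of the common dispersion was 0.756, which is the spread of a typical miRNA between libraries of a group as a share of its mean. The median SE of a log2 fold change was 0.825, 0.823 and 0.825 in the 3 comparisons. CPM values are TMM-normalised counts of mature miRNA. Values per library, such as the number of miRNAs detected, were compared by two-sided exact permutation tests, which cannot give a p under 0.1 with 3 against 3. The p-values of single miRNAs and of values per library measure the spread between the libraries of a group. Those of the list test camera, described below, set a list's members against the other miRNAs. At the preset correlation they take the members as nearly independent. Permutation p-values of correlations come from rearranging libraries within groups.

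For each comparison the text names the miRNAs past the threshold with separate groups and at least 10 CPM, of which there were 0, the 10 with the lowest p, 2 to 4 of the most abundant members of each list, and the 10 most abundant miRNAs overall. The miRNAs named beyond these (miR-155-5p, miR-376c-3p, miR-7219-3p, miR-199b-3p, miR-486a-5p, miR-486b-5p, let-7a-1-3p, let-7c-2-3p, miR-532-5p, miR-3074-5p and those of calls under other settings) were chosen after their values were seen. The 17 lists were written from general knowledge: inflammation, myeloid, fibrosis and silicosis, silica and vesicles, let-7, miR-17~92, miR-15/16, miR-23/27/24, miR-30, miR-29, miR-181, Sfmbt2 (by the name prefixes miR-466, miR-467, miR-669 and miR-297, not by position), Dlk1-Dio3, serum and erythroid, and the epithelial, the mesenchymal and endothelial, and the muscle, neuron, liver and lymphocyte lists. The fibrosis and silicosis list and the silica and vesicle list come from memory of work on silicosis and may include miRNAs chosen from these same samples. Lists with at least 3 tested members (16) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and also with an estimated correlation and with fry; these are model p-values from edgeR and limma.

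Libraries with the same replicate number deviated together from their group means. For numbers 1, 2 and 3, r was 0.136, 0.439 and 0.149 for 24 h with untreated and 0.152, 0.636 and 0.315 for 48 h with untreated. A pairing by number is thus possible. The main fit has no block, and the number was fitted as a block among the alternatives. Deviations cancel within a group of 3, so the strong match at number 2 also moves the values of the other numbers. The labels state no pairing, and some libraries with different numbers reached as much (0.16 and 0.360 at the highest). With the number as a block, edgeR called 3 miRNAs at 24 h and 0 at 48 h against untreated. Libraries of one group were not duplicates: chi-square per degree of freedom between them was 284 to 3744, far above the 1 of sampling noise.

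Other ways of processing chosen in advance were other scalings (DESeq2 size factors, upper-quartile factors, total counts), other filters (none, or a mean of 10 CPM), DESeq2 and limma-voom, only the 2 groups compared, the block, a minimum of 2-fold, all features, at least 10 counts for detection, thinning to 2158418 counts, and leaving out each library. Those meant for normalised values (a pseudocount and a filter) did not apply. Chosen after seeing the data were the sums of miRNAs sharing 20 bases, limma-voom with quality weights, a robust edgeR fit, the fits without the libraries numbered 2 or without untreated 2 and 48 h 2, the block with only 2 groups, and the scalings and left-out libraries for the lists.

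On simulated data with the real means, library sizes and dispersions (20 datasets of 453 miRNAs, 200 changed), the test of 24 h against untreated called 4.89% of miRNAs changed 2-fold, 26.7% of those changed 4-fold and 84.1% of those changed 16-fold, and 2.56% of its calls were unchanged. For 48 h against 24 h the shares were 3.47%, 26.0% and 83.2%, with 2.29% unchanged among the calls. With 200 of 453 changed, the Benjamini-Hochberg threshold is easier to reach than where few miRNAs change. Fewer changed miRNAs were not simulated, so these shares may be too high for the real data. A list of 11 members changed 2.5-fold at 24 h was recovered in 16 of 20 datasets, and 1 of 300 unchanged lists was called. The simulated miRNAs were drawn independently of each other. In the real data the estimated correlation between members at 24 h ran from -0.010 in the mesenchymal and endothelial list to 0.904 in miR-15/16, with 0.159 in Dlk1-Dio3. The simulated list calls therefore do not cover lists whose members move together. Hairpin positions are from the GENCODE annotation of mm10. The tools were edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.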

Results

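Small RNA was sequenced from exosomes, the small vesicles that cells release into their medium. The vesicles came from RAW264.7 cells, a mouse macrophage line, and silica is the mineral dust whose inhalation leads to the lung disease silicosis. The 3 groups were untreated cells, cells kept with silica for 24 h and cells kept with silica for 48 h, with 3 libraries in each group. The culture time of the untreated cells was not given in the sources used here. The libraries held 7706904 to 18654539 counted reads, of which mature miRNAs took 2158418 to 8331451, or 28.01% to 44.7%. A count of 3 in a library corresponds to 0.360 to 1.39 CPM of mature miRNA, and such floors and the intervals given for low counts cover counting error only. Of 1101 mature miRNAs listed in at least 1 library, 362 were listed in all 9 libraries. The number detected per library averaged 659 ± 147 in untreated, 598 ± 114 at 24 h and 717 ± 169 at 48 h (SD, n = 3), with a two-sided exact permutation p of 0.7 for 24 h against untreated, 0.5 for 48 h against untreated and 0.4 between the times.

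The vesicle cargo was led by let-7c-5p, miR-99a-5p and miR-23a-3p, with means over the 9 libraries of 105541, 79932 and 73221 CPM. They were followed by miR-222-3p, miR-146a-5p, an NF-kappaB-induced brake on inflammatory signalling, miR-27a-3p, miR-24-3p, miR-27b-3p, miR-7a-5p and miR-21a-5p, an abundant miRNA of activated myeloid cells. The 10 most abundant miRNAs of each library, not always the same 10, together took 59.1% ± 3.76 of mature counts in untreated, 60.5% ± 2.48 at 24 h and 58.9% ± 3.25 at 48 h (SD, n = 3). None of the 10 miRNAs named above passed the test in any comparison. The haematopoietic miR-223-3p stood at 107 ± 49.9, 165 ± 20.8 and 105 ± 55.1 CPM in untreated, 24 h and 48 h.

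The libraries did not group by treatment alone. In the multidimensional scaling, the untreated library 2 and the 48 h library 2 lay apart from the other 7, and they were the most similar of all pairs of libraries (r = 0.969 across miRNAs, which are not independent replicates). These 2 libraries also listed the most mature miRNAs, 829 and 912. The 24 h library 3 lay at the opposite end of dimension 1, at 1.13. Its r with untreated library 2, 0.818, was the lowest of all pairs. It held the fewest mature counts, 2158418, and listed the fewest mature miRNAs, 486. It stayed the lowest after every library was thinned to that depth.

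**Figure D1:**
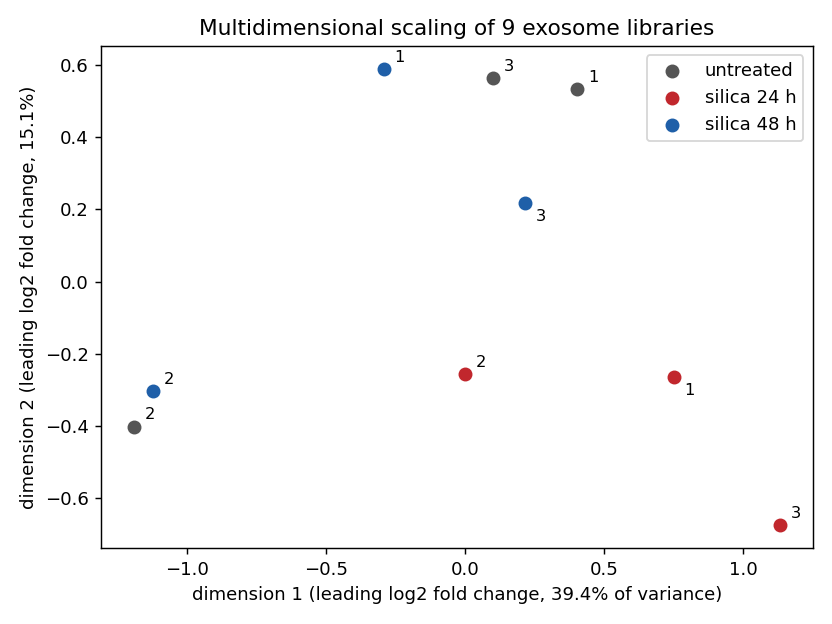
Multidimensional scaling of the 9 exosome libraries on mature miRNAs, with 1 point per library, coloured by group and marked with its replicate number; the axes are leading log2 fold changes, and dimensions 1 and 2 hold 39.4% and 15.1% of the variance. The untreated library 2 and the 48 h library 2 sit together at the left, at -1.19 and -1.12 on dimension 1, and the 3 libraries of 24 h lie at 0.75, 0.00 and 1.13.

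The comparison of 24 h of silica with untreated cells addressed which vesicle miRNAs differ after the shorter exposure. The miRNAs of the imprinted Dlk1-Dio3 cluster on chromosome 12 were higher as a group at 24 h by limma's camera (adjusted p = 0.00154, but 0.607 with an estimated correlation), with 10 of 11 tested members higher and a median log2 fold change of 1.09. No single miRNA of the 453 tested passed an adjusted p of 0.05. The lowest p belonged to miR-532-3p, which had 0 counts in the 3 libraries of 24 h and 514 in untreated, where it averaged 32.2 ± 19.4 CPM (SD, n = 3). This is at least 129.7-fold lower at 24 h, taken against 3 counts over the group, with an adjusted p of 0.102 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other arm of the same hairpin, miR-532-5p, had 1558, 35200 and 13129 counts at 24 h and 926, 17089 and 20995 in untreated. The 0 counts at 24 h thus hold for the 3p arm alone. Without passing the test, miR-143-3p, a miRNA of smooth muscle and other mesenchymal cells, stood at 4.51-fold and miR-451a, the main miRNA of red blood cells, at 4.39-fold of the untreated level.

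Over the 453 miRNAs, edgeR's quasi-likelihood test called 0, with 46 at an unadjusted p under 0.05 (25 higher and 21 lower) where chance gives 22.7 for independent libraries. DESeq2 called 4 and limma-voom 0. All libraries of one group lay above all of the other for 75 miRNAs, 47 higher and 28 lower at 24 h. This is 16.6% of those tested where chance gives 10% for independent libraries, while same-numbered ones here may be related. After miR-532-3p, the next lowest p belonged to miR-219a-5p, with 2 counts at 24 h and 247 in untreated, a ratio of 93.5 with a 95% counting interval of 25.6 to 776 that leaves out the spread between libraries (edgeR adjusted p = 0.318, Benjamini-Hochberg). Of the 247 counts, 205 came from the untreated library 2 (untreated mean 14.6 ± 17.7 CPM, SD, n = 3), without which its log2 fold change went from -6.39 to -4.64. The other 8 of the 10 lowest all had an edgeR adjusted p of 0.386. In this set miR-140-3p stood at 161 ± 15.7 CPM at 24 h and 623 ± 260 in untreated (log2 fold change -1.95 ± 0.54, SE), and miR-674-3p at 12.8 ± 10.2 and 71.3 ± 31.1 CPM. On the higher side, miR-382-5p stood at 8.81 ± 4.74 and 0.30 ± 0.35 CPM, miR-143-3p at 68.7 ± 24.6 and 15.2 ± 9.14, and miR-149-5p at 121 ± 38.2 and 30.9 ± 11.99. Likewise miR-191-3p stood at 579.7 ± 88.4 and 149 ± 64.6 CPM, let-7d-3p at 2248 ± 1756 and 319 ± 228, and miR-451a at 1953 ± 1290 and 444 ± 260. The log2 fold change of let-7d-3p went from 2.82 to 1.99 without the 24 h library 3. The hairpin of miR-532-3p lies at chromosome X 7248402 to 7248497 in an intron of Clcn5 (mm10). That of miR-140-3p lies at chromosome 8 107551244 to 107551313 in exonic sequence of Wwp2, and that of miR-143-3p at chromosome 18 61649196 to 61649258 between genes. The count of 0 became 3 with the replicate number as a block (miR-532-3p, miR-219a-5p and let-7d-3p), 7 without a filter on low counts, and 1 with upper-quartile factors, with only these 2 groups in the fit, or without the 48 h library 1 or the 48 h library 2, where the 1 was miR-532-3p each time.

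**Figure D2:**
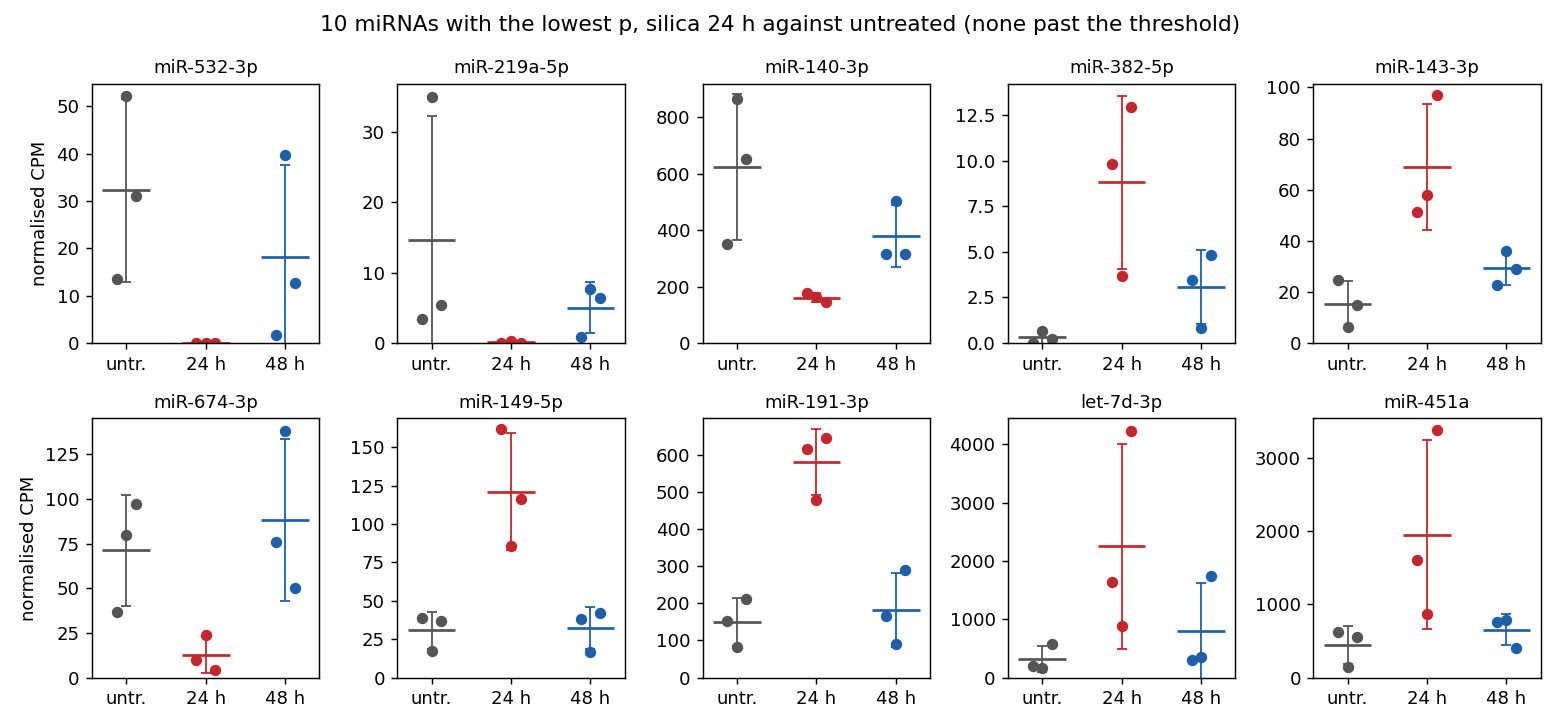
Normalised CPM (linear axes from 0) of the 10 miRNAs with the lowest p in the comparison of 24 h with untreated, with points for single libraries, horizontal lines for group means and error bars for the SD of 3 libraries. For miR-532-3p the 3 libraries of 24 h lie at 0 and the untreated mean is 32.2; none of the 10 passed an adjusted p of 0.05.

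The Dlk1-Dio3 list was the 1 of 16 tested lists that passed camera at 24 h (Benjamini-Hochberg over the lists). It did not pass with an estimated correlation, and the directional fry test gave an adjusted p of 0.213. Of the 34 miRNAs written into the list, 22 were listed in at least 1 library and 11 were tested. Among its members miR-411-5p stood at 71.7 ± 9.18 CPM at 24 h and 22.5 ± 16.5 in untreated, miR-127-3p at 41.3 ± 5.64 and 19.5 ± 16.5, and miR-379-5p at 26.1 ± 8.75 and 12.3 ± 12.6 (SD, n = 3). The 1 member with the other sign was miR-369-3p, at 13.5 ± 5.51 and 19.8 ± 18.1 CPM. The remaining tested members were scarce, with means over the 9 libraries from 1.9 CPM (miR-154-5p) to 8.32 CPM (miR-410-3p). By single miRNA, 0 of the 11 passed over all miRNAs and 1, miR-382-5p, passed when adjusted over the list alone, and 5 members had all 24 h libraries above all untreated ones. The hairpins of miR-379-5p, miR-411-5p and miR-382-5p lie at chromosome 12 109709060 to 109709125, 109710175 to 109710256 and 109733771 to 109733846, the first pair between genes and the last in an intron of Mirg. The list's level moved with 2 miRNAs of the serum and erythroid list, picked after values were seen: miR-122-5p, the main miRNA of liver, and miR-451a. Within groups, the deviations of the 9 libraries correlated at r = 0.968 and rho = 1 (exact permutation p = 0.00463 for each, the smallest that 216 arrangements within groups can give). This p does not allow for the choice of the pair. The other 4 members of the serum and erythroid list followed this pair at r = 0.325 (exact permutation p = 0.481). For the Dlk1-Dio3 list the p adjusted over the 16 lists compared in this way was 0.0741, and r was 0.913 without the 2 libraries farthest from the median. The call depended on the untreated library 2, without which the camera adjusted p was 0.164, while without any other single library it was 8.5e-05 to 0.011.

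**Figure D3:**
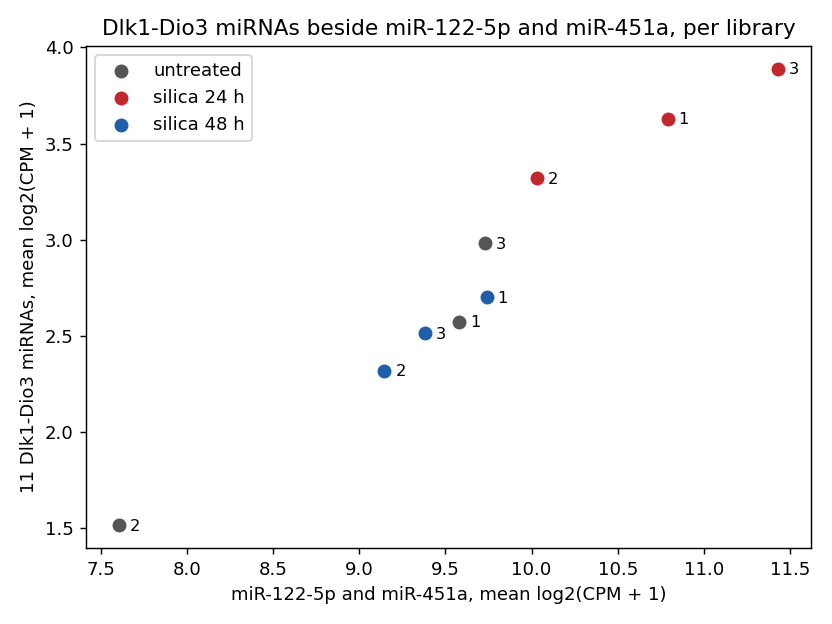
Mean log2(CPM + 1) of the 11 tested Dlk1-Dio3 miRNAs (vertical axis) against the mean log2(CPM + 1) of miR-122-5p and miR-451a (horizontal axis), with 1 point per library, coloured by group and marked with its replicate number. The 3 libraries of 24 h are highest on both axes, and the untreated library 2 is lowest on both, at 1.51 and 7.61.

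The other lists were described by the same tests at 24 h, and in all of them 0 members passed over all miRNAs. The miR-17~92 family, which promotes cell cycle entry, had 1 of 9 members higher and 8 lower (median -1.83, camera adjusted p = 0.0615), with miR-19b-3p at 648 ± 263 CPM against 2346 ± 2867 and miR-92a-3p, the member with the other sign, at 39399 ± 16791 against 23957 ± 1863. The miR-15/16 family, which restrains cell cycle entry, had 6 of 6 lower (median -1.32, camera adjusted p = 0.0615), with miR-16-5p at 9192 ± 552 CPM against 17260 ± 13462 and miR-15a-5p at 188 ± 54.3 against 1113 ± 1304. With an estimated correlation the adjusted p was 0.607 for both families. The miR-17~92 list passed with the replicate number as a block (camera adjusted p = 0.0209). Both families also passed when the untreated library 1 or 3 or any of the 3 libraries of 48 h was left out, with camera adjusted p of 0.0105 to 0.0496. Without the untreated library 2, one of the pair that lay apart, the medians were -0.08 for miR-17~92 and -0.14 for miR-15/16 with a camera adjusted p of 0.456 for both. The lower levels of both families at 24 h thus rest on that library.

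Among 15 tested miRNAs induced in inflammation, 6 were higher and 9 lower at 24 h (camera adjusted p = 0.948), and miR-155-5p and miR-146a-5p had log2 fold changes of -0.07 and -0.24. The median, the mean and the test of this list differed in sign, and its median of -0.08 turned positive under upper-quartile factors. Of 14 miRNAs of myeloid cells 5 were higher and 9 lower (0.843), and of 19 miRNAs linked to fibrosis or silicosis 3 were higher and 16 lower (0.166), with miR-21a-5p at 28777 ± 3820 CPM against 39615 ± 13141. Of 7 miRNAs recalled from work on silica and vesicles 4 were higher (0.800). These last 2 lists may include miRNAs chosen from the same samples and are not independent evidence of a direction. The let-7 family had 5 of 10 higher (0.843), with let-7c-5p at 140261 ± 19247 CPM against 76230 ± 26807, the miR-23/27/24 clusters 3 of 11 (0.344), the miR-30 family 1 of 7 (0.344), the collagen-targeting miR-29 family 2 of 6 (0.166), and the miR-181 family 3 of 5 (0.843). In the miR-23/27/24 clusters miR-24-3p stood at 11613 ± 1392 CPM against 55576 ± 56836. The untreated library 1 held 650736 of its counts, against 125317 and 106310 in the other untreated libraries, and the log2 fold change of -2.26 ran from -2.79 to -1.04 over the alternatives. Of the miRNAs whose names begin with miR-466, miR-467, miR-669 or miR-297, many of them from a cluster in the Sfmbt2 gene, 1 of 26 listed was tested. This was miR-466i-5p, whose annotated hairpin lies outside that gene, on chromosome 13, with a log2 fold change of 0.70 at 24 h, 0.06 at 48 h and -0.64 between the times.

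Lists for sources other than macrophages gave the following at 24 h, each value in brackets being the camera adjusted p. The serum and erythroid list had 4 of 6 higher (0.204), with miR-122-5p at 1820 ± 515 CPM against 825 ± 528 and miR-320-3p at 3858 ± 365 against 4108 ± 494. The epithelial list had 3 of 10 higher (0.427), with miR-183-5p at 6920 ± 1568 CPM against 5824 ± 2770. The mesenchymal and endothelial list had 6 of 9 higher (0.166, 0.607 with an estimated correlation, and 0.0465 without the untreated library 3), and 1 member, miR-143-3p, passed when adjusted over the list alone. The list for muscle, neurons, liver and lymphocytes had 5 of 8 higher (0.919), its median and mean differed in sign, and 1 member, miR-219a-5p, passed when adjusted over the list alone. When adjusted over the list alone, 0 members of any of the other lists passed at 24 h.

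The comparison of 48 h of silica with untreated cells addressed the longer exposure. The median size of the log2 fold change was 0.37, against 0.69 at 24 h, and these sizes were not compared by a test. The 48 h and the untreated group each hold 1 of the 2 libraries that lay apart and resembled each other most. The lowest p belonged to miR-378d, at 7.86 ± 2.90 CPM at 48 h and 999 ± 1036 in untreated (SD, n = 3). The pancreatic islet miRNA miR-375-3p stood at 8.26 ± 4.8 CPM against 2.29 ± 0.44, and miR-382-5p of the Dlk1-Dio3 cluster at 3.05 ± 2.03 against 0.30 ± 0.35.

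Here edgeR's quasi-likelihood test called 0 of 453 miRNAs, with 4 at an unadjusted p under 0.05 (2 higher and 2 lower), and the lowest adjusted p was 0.997 (Benjamini-Hochberg). Chance gives 22.7 for independent libraries, but same-numbered libraries here may be related. The 3 other splits that part the same-numbered libraries, looked at after the result, gave 1 to 5. DESeq2 called 1, miR-378d, as did the edgeR fit without a filter on low counts, and limma-voom called 0. The groups were separate for 17 miRNAs, 10 higher and 7 lower, which is 3.75% where chance gives 10% for independent libraries. In the untreated group miR-378d itself ranged from 15.1 to 2081 CPM, and its log2 fold change went from -6.98 to -5.84 without the untreated library 2. Among the 10 lowest p, miR-328-3p stood at 296 ± 64.2 CPM at 48 h against 147 ± 17.2, miR-872-5p at 564 ± 104 against 1090 ± 291, and miR-702-5p at 76.5 ± 47.7 against 196 ± 106. Lower values also stood for miR-5114, at 24.4 ± 8.68 CPM against 60.2 ± 16.2, and miR-330-3p, at 21.1 ± 7.02 against 47.8 ± 23.5. With few counts, miR-3086-5p had 1 count at 48 h and 14 in untreated, a ratio of 15.5 with a 95% counting interval of 2.36 to 657 (log2 fold change -3.34, and -1.87 without the untreated library 1), and miR-154-5p had 2 and 35, a ratio of 19.4 with an interval of 4.99 to 167.

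At 48 h, 0 of the 16 tested lists passed camera (lowest adjusted p 0.791), also with an estimated correlation and with fry, and 0 members of any list passed when adjusted over the list alone. The inflammation list had 11 of 15 members higher, with miR-125a-5p at 623 ± 355 CPM against 291 ± 29.7 (SD, n = 3) and miR-222-3p at 46599 ± 9458 against 40426 ± 11958. The let-7 family had 9 of 10 higher, the miR-30 family 7 of 7, with miR-30d-5p at 3569 ± 965 CPM against 2493 ± 697, and the miR-29 family 5 of 6, with miR-29a-3p at 5146 ± 3065 against 3726 ± 2172. The Dlk1-Dio3 list had 7 of 11 higher (median 0.25, mean -0.09, adjusted p 0.854), the serum and erythroid list 1 of 6, with miR-122-5p at 817 ± 361 CPM against 825 ± 528, and the list for muscle, neurons, liver and lymphocytes 2 of 8. Higher members numbered 7 of 14 in the myeloid list, 10 of 19 in the fibrosis list, 5 of 7 in the silica and vesicle list, 6 of 9 in miR-17~92, 4 of 6 in miR-15/16, 6 of 11 in miR-23/27/24, 4 of 5 in miR-181, 7 of 10 in the epithelial list and 4 of 9 in the mesenchymal and endothelial list. In the silica and vesicle list miR-7219-3p had a log2 fold change of 1.16. The median, mean and test differed in sign for the myeloid, fibrosis, miR-17~92, miR-15/16, Dlk1-Dio3 and mesenchymal lists, and the medians of the myeloid, fibrosis, miR-17~92, miR-23/27/24 and mesenchymal lists changed sign under another scaling.

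The comparison of 48 h with 24 h tested the difference between the exposures directly. The Dlk1-Dio3 miRNAs were lower as a group at 48 h than at 24 h by limma's camera (adjusted p = 0.00792, but 0.526 with an estimated correlation), with 9 of 11 members lower and a median log2 fold change of -1.46. No single miRNA of 453 passed an adjusted p of 0.05. The lowest p belonged to miR-532-3p, with 440 counts at 48 h and 0 at 24 h. Over pooled counts this is at least 100.1-fold higher at 48 h against 3 counts over the group (edgeR adjusted p = 0.183, Benjamini-Hochberg). The 48 h library 2, which lay apart with untreated library 2, held 379 of the 440 counts. The 48 h libraries 1 and 3 held 6 and 55. The log2 fold change of 9.50 ran from 5.75 to 10.1 over the alternatives. In the 48 h libraries miR-532-3p ranged from 1.73 to 39.7 CPM. The other arm of its hairpin, miR-532-5p, had 17190, 1616 and 23335 counts at 48 h and 1558, 35200 and 13129 at 24 h. Lower at 48 h with low p stood miR-139-5p, at 3194 ± 2603 CPM against 16468 ± 4503 at 24 h (SD, n = 3).

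Here edgeR's quasi-likelihood test called 0, with 44 at an unadjusted p under 0.05 (25 higher and 19 lower) where chance gives 22.7 for independent libraries. DESeq2 called 6 and limma-voom 0. The groups were separate for 94 miRNAs, 47 in each direction, which is 20.8% where chance gives 10% for independent libraries. The other 9 of the 10 lowest p had edgeR adjusted p of 0.404. Among them miR-2137 stood at 19.2 ± 9.24 CPM at 48 h and 157 ± 27.04 at 24 h, miR-149-5p at 32.5 ± 13.7 and 121 ± 38.2, miR-5099 at 1868 ± 1143 and 7464 ± 2498, and miR-5119 at 0.87 ± 1.25 and 32.1 ± 43.9. On the higher side, miR-674-3p stood at 88.1 ± 45.4 and 12.8 ± 10.2 CPM, and miR-24-3p at 58608 ± 51064 and 11613 ± 1392. Single libraries weighed on some of these: the log2 fold change of miR-5119 went from -5.17 to -2.95 without the 24 h library 3, which held 159 of its counts at 24 h against 45 and 13, and that of miR-24-3p from 2.34 to 1.43 without the 48 h library 1. With few counts, miR-3086-5p had 1 count at 48 h and 65 at 24 h, a ratio of 95.3 with a 95% counting interval of 16.5 to 3820, and miR-219a-5p had 104 and 2, a ratio of 35.5 with an interval of 9.58 to 297. The hairpin of miR-139-5p lies at chromosome 7 101475376 to 101475443 in an intron of Pde2a, and that of miR-2137 at chromosome X 72992079 to 72992144 in an intron of Zfp185. The count of 0 became 16 without a filter on low counts, and 1, miR-532-3p, without the 48 h library 1. With the replicate number as a block, miR-106b-5p, miR-2137 and miR-532-3p passed, and more passed with the block and only these groups. Whether the numbers pair these libraries is open. Their deviations correlated at -0.068, 0.289 and 0.253 for numbers 1, 2 and 3, and at 0.0813 at most for different numbers.

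Between the times, the Dlk1-Dio3 list was again the 1 of 16 lists past camera (adjusted p = 0.00792, but 0.526 with an estimated correlation), and the directional fry test gave an adjusted p of 0.244. Of its members miR-379-5p stood at 5.19 ± 2.29 CPM at 48 h against 26.1 ± 8.75 at 24 h and miR-411-5p at 26.1 ± 13.8 against 71.7 ± 9.18 (SD, n = 3), while miR-369-3p and miR-376c-3p had the other sign. The list call was lost without the untreated library 1 (camera adjusted p = 0.0553), the 24 h library 2 (0.0825), the 24 h library 3 (0.0594) or the 48 h library 2 (0.064). The serum and erythroid list had 6 of 6 lower (median -1.03, camera adjusted p = 0.0733), with miR-451a at 652 ± 211 CPM against 1953 ± 1290 and miR-122-5p at 817 ± 361 against 1820 ± 515. The miR-29, miR-15/16 and miR-30 families had 6 of 6, 6 of 6 and 7 of 7 higher and miR-17~92 had 7 of 9 higher, each with a camera adjusted p of 0.0696. The miR-29, miR-15/16 and miR-17~92 families passed without the untreated library 2, the 48 h library 1 or the 48 h library 3 (0.0202 to 0.0421) and the fibrosis list without the 48 h library 3 (0.0444). The miR-30 family passed without the libraries numbered 2 (camera adjusted p = 0.0122) and without untreated 2 and 48 h 2 (0.0319), but in none of the fits that left out a single library. With all libraries and an estimated correlation, the adjusted p of these 5 lists was 0.526 to 0.536. Without the 48 h library 2 the medians of miR-17~92, miR-15/16 and miR-29 went from 1.80, 1.46 and 1.42 to 0.06, 0.32 and 0.74, with camera adjusted p of 0.304, 0.451 and 0.220, and the log2 fold change of miR-19b-3p went from 2.33 to 0.06. That library held 80153 counts of miR-19b-3p, against 2757 and 2475 in the other libraries of 48 h. Examples are miR-29c-3p, at 244 ± 256 CPM against 42.9 ± 8.39, miR-15a-5p, at 1042 ± 1185 against 188 ± 54.3, and miR-19b-3p, at 3256 ± 4456 against 648 ± 263. The remaining lists had adjusted p of 0.111 to 0.957, with 11 of 15 members higher in the inflammation list, 7 of 14 in the myeloid, 14 of 19 in the fibrosis, 5 of 7 in the silica and vesicle, 7 of 10 in the let-7, 7 of 11 in the miR-23/27/24, 3 of 5 in the miR-181, 7 of 10 in the epithelial, 2 of 9 in the mesenchymal and 3 of 8 in the muscle, neuron, liver and lymphocyte list. Signs of median, mean and test differed for the myeloid, miR-181 and muscle lists, the miR-181 median changed sign under another scaling, and 0 members of any list passed when adjusted over the list alone.

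Of the most abundant members of the lists not given above, 0 passed in any comparison. Their log2 fold changes at 24 h and at 48 h against untreated were 0.67 and 0.27 for let-7b-5p, -0.10 and 0.16 for let-7i-5p, -0.61 and 0.02 for miR-96-5p, 0.21 and -0.21 for miR-126a-3p, -0.99 and 0.16 for miR-15b-5p, -0.37 and -0.43 for miR-93-5p, 0.25 and 0.30 for miR-181a-5p, -0.22 and -0.40 for miR-181b-5p, -0.03 and 0.51 for miR-30a-3p, and -0.08 and 0.22 for miR-128-3p. Between the times they were -0.40, 0.26, 0.63, -0.42, 1.15, -0.07, 0.06, -0.18, 0.55 and 0.30 in the same order. Among the 10 most abundant miRNAs, miR-99a-5p had 0.15 at 24 h and 0.11 at 48 h, miR-23a-3p 0.45 and 0.17, miR-27a-3p -0.59 and -0.39, miR-27b-3p -0.56 and -0.13, and miR-7a-5p -0.69 and -0.23.

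The effects at 24 h and 48 h were set against each other over the 453 miRNAs, which are not independent replicates. Their log2 fold changes correlated at r = 0.198, below the 0.495 ± 0.0547 (SD) of 100 simulations in which neither group differed from the shared untreated libraries. The simulated libraries are independent, while real ones of the same replicate number may be related. No simulation with related libraries was run, so the simulated value is not a no-change value for such libraries. Regrouping the 9 real libraries at random 100 times gave a mean r of 0.471 (range 0.00 to 0.872), with 6 regroupings as low as the observed one. The covariance was 0.223 against 0.495 ± 0.0821 simulated, a difference of -0.27, and the sign was shared by 54.3% of miRNAs against 66.5% simulated. In both comparisons miR-375-3p and miR-382-5p had an unadjusted p under 0.05 and were higher, and 0 miRNAs were lower in both. The number shared by chance was not simulated, and miR-382-5p had 0, 4 and 1 counts in the untreated libraries, which enter both folds. The 3 untreated libraries are too few to be split, so the part due to sharing them was not removed. The correlation was -0.00 without the 48 h library 3, 0.297 without the 24 h library 1, 0.307 without the 24 h library 3, 0.370, 0.571 and 0.388 without the untreated libraries 1, 2 and 3, and 0.398 without the 48 h library 2.

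Other RNA classes were compared as shares of all counted reads. Reads assigned to exons took 10.5% ± 0.502 at 24 h, 7.71% ± 0.221 in untreated and 6.71% ± 0.687 at 48 h (SD, n = 3), and small nucleolar RNA took 0.642% ± 0.0805, 0.359% ± 0.0998 and 0.360% ± 0.101. For both classes all 24 h libraries lay above all libraries of the other groups (two-sided exact permutation p = 0.1 for each comparison with 24 h, the smallest that 3 against 3 allow, and 0.66 after Benjamini-Hochberg adjustment over 66 tests). Repeats took 24.4% ± 2.09 in untreated, 23.9% ± 0.491 at 24 h and 27.2% ± 0.793 at 48 h, and introns 11.97% ± 1.61, 14.1% ± 2.97 and 9.84% ± 1.06.

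The counts of some miRNAs whose hairpin arms share 20 bases switched between libraries. The mature sequences themselves were not compared. The pair miR-199a-3p and miR-199b-3p summed to 550 to 1543 CPM in the 9 libraries, while the log2 ratio of the first to the second ran from -5.66 to 6.42. In untreated libraries 1 and 2 nearly all of the sum was listed under miR-199b-3p and in untreated library 3 under miR-199a-3p, and both kinds of library also occurred at 24 h and at 48 h. Values of single members of this pair are therefore uncertain. The log2 ratio of let-7a-1-3p to let-7c-2-3p was less steady still, from -7.74 to 6.65. That of miR-24-3p to miR-3074-5p, whose hairpin arms share 20 bases on opposite strands, ran from 2.4 to 13.8. In this pair miR-24-3p was the higher in every library, so the ratio varied without a switch. Among the pairs sharing 20 bases, the steadiest ratio was that of miR-29b-3p to miR-29c-3p, from -2.02 to -0.89 in log2.

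**Figure D4:**
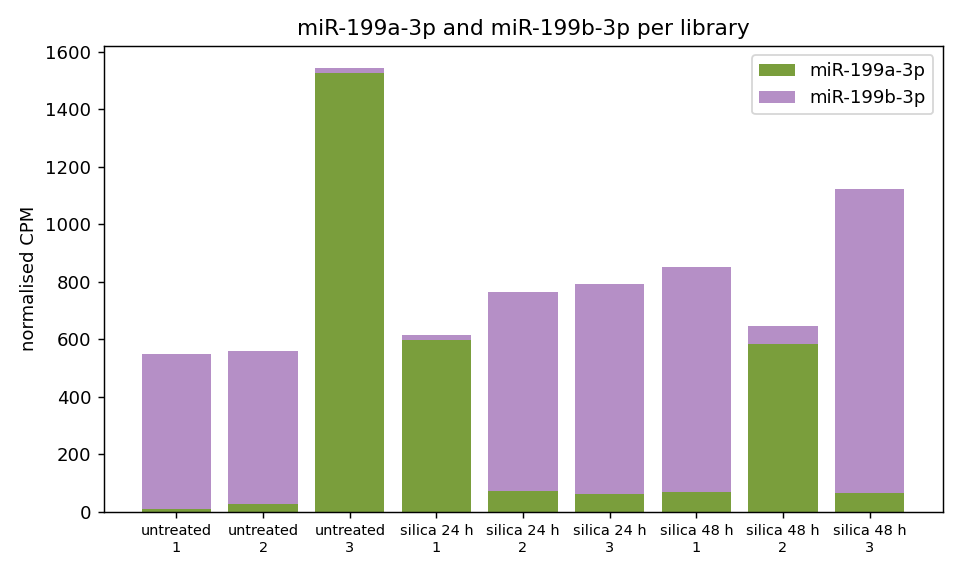
Normalised CPM of miR-199a-3p (green) and miR-199b-3p (purple), stacked from 0, in each of the 9 libraries. In 3 libraries, untreated 3, 24 h 1 and 48 h 2, most of the sum is under miR-199a-3p, and in the other 6 under miR-199b-3p.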

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

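All tests of explanations in this part were chosen after the results were seen. The bounds for 2 of them, on serum RNA and on the libraries that stand apart, were also changed after their values had been seen. Under the first bounds serum RNA would have counted as met and the libraries that stand apart as argued against, and under the changed ones both stay open.

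The Dlk1-Dio3 miRNAs differed between the exposure times: in the direct test of 48 h against 24 h the camera adjusted p was 0.00792 (0.526 with an estimated correlation), with 9 of 11 members lower and a median log2 fold change of -1.46. Against untreated cells the median was 1.09 at 24 h and 0.25 at 48 h. The call was lost without the untreated library 1 (0.0553), the 24 h library 2 (0.0825), the 24 h library 3 (0.0594) or the 48 h library 2 (0.064). It was kept without untreated 2 and 48 h 2 together (0.0153) and without the 3 libraries numbered 2 (0.0122).

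One hypothesis for the higher Dlk1-Dio3 level at 24 h is RNA carried over from the fetal bovine serum of the medium. Within groups that level followed miR-122-5p and miR-451a, a pair picked from the serum list after values were seen, at r = 0.968. Of 10000 random lists matched on abundance, 1 did so as closely (median r -0.44). Their members were drawn singly and lack the shared movement of a cluster, so they give no share expected by chance. The other lists followed the pair at r from -0.878 for the silica and vesicle list (exact permutation p adjusted over 16 lists 0.0952) to 0.663 for the muscle, neuron, liver and lymphocyte list (0.156). The other 4 members of the serum and erythroid list had a median log2 fold change of 0.08 at 24 h, from -0.13 for miR-486a-5p to 0.94 for miR-486b-5p, and followed that pair at r = 0.325 (exact permutation p = 0.481), so whether the pair stands for serum is not settled and serum may account for all, part or none of the pattern. A second candidate explanation for the level at 24 h, that the libraries that stand apart made it, is also open. Without untreated 2 and 48 h 2 the median went from 1.09 to 0.749 and the camera adjusted p from 0.00154 to 0.105, with fewer libraries in the fit. The SE of the mean over members was 0.413, taken from the fit with all libraries and treating members as independent. Other values also stood higher at 24 h, the mesenchymal and endothelial list with the same median of 1.09 (camera adjusted p 0.166, not passing) and the shares of exon reads (10.5% against 7.71% in untreated) and small nucleolar RNA (0.642% against 0.359%), and whether they share a cause with the Dlk1-Dio3 list was not tested. An effect of silica at 24 h remains among the open explanations. It cannot be told from time in culture, since the culture time of the untreated cells was not given. These data cannot tell these explanations apart.

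The untreated library 2 and the 48 h library 2 stood apart from the other libraries, with deviations from their group means that correlated at r = 0.636 over miRNAs. The 24 h library 3 lay at the opposite end of the multidimensional scaling, and explanations for its position were not tested. Depth is argued against: after thinning every library to 2158418 counts, both still listed at least 132.4 miRNAs more than the highest of the 6 libraries numbered 1 or 3, while the 24 h library 2, left out of that comparison, came closer (663 against 717 for the lower of the pair). GC content was taken from the hairpin arm, which is longer than the mature miRNA that was sequenced. On the 429 of 453 miRNAs with a value the correlation was 0.625 before and 0.618 after a trend on arm GC was removed. A trend on arm GC is thus argued against. Arm GC itself correlated with the deviations of untreated 2 and 48 h 2 at only -0.138 and -0.099. The GC content of the mature miRNAs was not measured and stays open. That libraries of the same number were handled together could not be settled: the 24 h library 2 deviated with both, at 0.289 or more, but the highest of 18 pairs with different numbers reached 0.360. Explanations in the cells themselves were not tested.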

How the results depend on the processing

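Chosen after the results were seen were the sums of miRNAs sharing 20 bases, limma-voom with quality weights and the robust edgeR fit. So were the fits without the libraries numbered 2, without untreated 2 and 48 h 2, and with the block and only 2 groups. All those for lists other than the estimated correlation and the block were also chosen then. For 24 h against untreated, the 0 called miRNAs became 1 with upper-quartile factors, 7 without a filter on low counts, 4 with DESeq2, 1 with only the 2 groups compared, 3 with the replicate block and 4 with the replicate block and only the 2 groups. For 48 h against untreated they became 1 without a filter and 1 with DESeq2. For 48 h against 24 h they became 16 without a filter, 6 with DESeq2, 3 with the replicate block and 8 with the block and only the 2 groups. Between these times, same-numbered libraries deviated together for numbers 2 and 3 (r = 0.289 and 0.253) but not for number 1 (r = -0.068). Different numbers reached 0.0813 at the highest, so whether the numbers pair these libraries is open. Leaving out single libraries gave 0 to 1 for 24 h (1 without 48 h 1 or 48 h 2) and 0 to 1 between the times (1 without 48 h 1). All other alternatives gave 0 as well, and the cause of the differences was not tested.

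Lists past camera numbered 1 at 24 h and 1 between the times. They became 0 and 0 with an estimated correlation, 2 and 2 with the replicate block (Dlk1-Dio3 and miR-17~92 in both), 0 and 2 without the libraries numbered 2, and 0 and 2 without untreated 2 and 48 h 2 (Dlk1-Dio3 and miR-30 in both). Leaving out single libraries gave 0 (without untreated 2) to 4 (without untreated 3) at 24 h, with 3 without untreated 1 or any 48 h library, and 0 (without 24 h 2, 24 h 3, 48 h 2 or untreated 1) to 5 (without 48 h 3) between the times, with 4 without 48 h 1 or untreated 2. The block changed no other call. The correlation of the 24 h and 48 h effects was 0.446 without the libraries numbered 2 and 0.561 without untreated 2 and 48 h 2, and ran from -0.00311 (without 48 h 3, reversed) to 0.571 (without untreated 2); the cause was not tested.

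Over the 30 results for the 10 lowest p of each comparison, 694 of 732 alternatives stayed on the same side of the threshold and 38 came past it, with 0 reversed. Of the 240 log2 fold changes of named miRNAs, 109 changed sign under some alternative, 10 of them from beyond 1 SE of 0. Upper-quartile factors moved the median log2 fold change by 0.158 at 24 h and by -0.11 between the times, and 7 of 48 list medians changed sign under some scaling. The differences in the number of miRNAs detected, -61 at 24 h, 58 at 48 h and 119 between the times, kept their direction but shrank to -11.7, 2 and 13.7 with at least 10 counts and to -27.1, 25.6 and 52.8 after thinning. Counts of 0 to 2 over a group limit miR-532-3p, miR-219a-5p, miR-3086-5p and miR-154-5p, whose folds rest on bounds or wide intervals.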

Other observations

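All tests of explanations and splits in this part were chosen after the results were seen.

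Predicted miRNAs outside the known set were listed from 10 counts: 783 ± 623 in untreated, 770 ± 408 at 24 h and 257 ± 229 at 48 h (SD, n = 3; two-sided exact permutation p = 1 for 24 h against untreated, 0.3 for 48 h against untreated and 0.2 between the times), with 99 in the 48 h library 1 and 1385 in the untreated library 1. They took 0.194% ± 0.0538, 0.273% ± 0.0925 and 0.134% ± 0.0454 of all counted reads.

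Counts switched between some miRNAs whose hairpin arms share 20 bases. For miR-199a-3p and miR-199b-3p the SD of the log2 ratio over the 9 libraries was 4.61 and that of the log2 sum 0.491, a quotient of 9.37. For let-7a-1-3p and let-7c-2-3p the quotient was 12.5. For miR-24-3p and miR-3074-5p, whose hairpin arms share bases on opposite strands, it was 3.44. In this last pair the log2 sum was less steady (SD 1.33) and miR-24-3p was the higher in every library, so its counts did not switch. Silica as the cause is argued against for the miR-199 pair. Each group's range of its log2 ratio was covered by that of each other group to at least 59.6%. For this pair, that reads matching both miRNAs were given to only 1 of them per library is the candidate explanation whose requirement was met. The requirement was a quotient over 3, a bound set on the same data after the switch was seen.

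Other splits of the 6 libraries of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. For called miRNAs, all 10 splits gave as many as the real 0 in each of the 3 comparisons, with 1, 1 and 0 in the highest other split. For miRNAs at an unadjusted p under 0.05, as many as the real 46, 4 and 44 came in 2, 9 and 2 splits, with 56, 102 and 61 in the highest other. For lists past camera, as many as the real 1, 0 and 1 came in 4, 10 and 5 splits, with 1, 4 and 2 in the highest other. The split with 102 set 48 h 1, 48 h 2 and untreated 2 against the rest, which points to a structure of the libraries across the groups. Among the 3 other splits that part all same-numbered pairs, miRNAs at an unadjusted p under 0.05 numbered 6 to 13 for 24 h against untreated and 1 to 5 for 48 h, and lists past camera 0 to 1 in both.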
